A study of Homo sapiens with 6 samples.

How the data were processed

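Gene expression was measured in HCT116 cells, a human colorectal carcinoma line, on 6 single-channel Affymetrix arrays. Per the labels' protocols, cells were transfected with 30 nM of a pool of siRNAs against CDK4 together with 30 nM of a siRNA against CDK6, or with 30 nM each of the corresponding 2 control siRNA products, and total RNA was taken 96 h later. The labels call the 3 arrays of each group biological replicates. They do not say whether these came from separate cultures started on separate days, so the p-values measure the spread between these arrays.

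The deposited values are on a log2 scale, and the submitters' processing notes name RMA, the robust multi-array average, which corrects background, equalises the distributions between arrays and summarises the probes of each probe set. Its version and any filter on probes are not given in the sources used here. Since RMA makes the distributions alike, a change in total RNA per cell cannot be seen in these values, and a fold change is relative to the bulk of the probe sets on the array. RMA also compresses changes of dim probe sets. The number of arrays limits the precision, and no detection calls were used.

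The table held 54675 probe sets, of which 62 were array controls. The platform annotation gave 1 gene symbol to 41097 probe sets, several to 1801 and none to 11777. Probe sets with 1 symbol that were not controls, 41091 in all, were used for genes. The symbols of 41037 of these were found by gene identifier in a RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed an update. That table served only for names and for the order of neighbouring genes, and no genome build was named by the files. For each gene the probe set with the highest mean over the 6 arrays stood for the gene, which left 19775 genes, 10523 of them with more than 1 probe set. No filter on dim genes was applied.

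The comparison was CDK4/6 siRNA minus control siRNA, fitted per gene with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment over all genes. A gene was called changed at an adjusted p under 0.05. Single values such as the spike-in mean were compared by a two-sided exact permutation test, for which 3 arrays against 3 cannot give a p under 0.1. Replicate numbers are shared between the groups in the labels without being said to mark a day or batch, so no block was used.

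Before the data were examined, 27 gene lists were written from general knowledge, together with the comparison, the alternatives and the rule for naming genes. The rule named CDK4, CDK6 and MYC, the 12 largest rises and 12 largest falls among called genes whose 3 values in each group did not overlap, leaving out placeholder names, and up to 4 members of each list with the smallest adjusted p. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 27 lists. Each list's members were also counted after adjustment over the list alone. A second camera test with the correlation estimated from the arrays, the rotation test fry and camera on ranks were alternatives. The estimated correlation rests on 6 arrays and is imprecise. For each list the median log2 fold change was also placed among 10000 random lists of the same size drawn from 50 bins of mean level.

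The other alternatives were the replicate number as a block, quantile normalisation, median centring or cyclic loess between arrays, leaving out the dimmest genes by mean level, the mean of all probe sets of a gene, every probe set tested separately, trend and robust options, array weights, a test without variance moderation, a threshold of 0.01 and each array left out in turn. Scaling to the hybridisation spike-ins, which are control RNAs added to the hybridisation mix, and using only probe sets with a plain name, without the suffix that marks probes shared between transcripts, were added after seeing the data.

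The fit was tested on simulated data with the same 19775 genes and 3 arrays per group. Of 100 genes changed by a log2 value of 0.5, 70% were called, and of 100 genes changed by 1, 99% were called. Of 177 calls, 8 were false. With no simulated change no gene and no list was called, and a list shifted by 0.3 was found. The noise was drawn separately for each gene, so genes of a list were uncorrelated there. The simulation therefore does not show how the list tests behave with correlated genes. Figures were drawn with matplotlib 3.10.9.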

Results

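HCT116 cells, an epithelial line from a colorectal carcinoma, were profiled 96 h after transfection with siRNAs against CDK4 and CDK6 or with control siRNAs, 3 arrays in each group. CDK4 and CDK6 are the kinases that bind D-type cyclins and phosphorylate the retinoblastoma protein in G1. The comparison addresses how gene expression adapts when they are targeted, and the series title names MYC in that response. Values are RMA expression on a log2 scale, and array medians lay between 5.36 and 5.39. Correlations between arrays across genes were 0.998 within groups and 0.991 to 0.994 between groups. The first principal component held 70.5% of the variance and separated the groups. Log2 fold changes are CDK4/6 siRNA minus control siRNA, n = 3 arrays per group, and the standard errors of the named called genes ran from 0.051 to 0.174.

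Both siRNA targets were lower in every CDK4/6 siRNA array than in any control array. CDK6 fell by 1.56 on the log2 scale (SE 0.055), to 34.0% of the control level, from 10.39 ± 0.04 to 8.84 ± 0.04 (SD). CDK4 fell by 0.69 (SE 0.082), to 62.2% of the control level, from 10.21 ± 0.12 to 9.52 ± 0.12 (SD). MYC, a transcription factor that drives growth and ribosome production, was already bright in control cells. It rose by 0.42 (SE 0.060), 1.34-fold, from 12.04 ± 0.07 to 12.45 ± 0.05 (SD). The limma adjusted p was 7.19e-06 for CDK6, 0.000431 for CDK4 and 0.00101 for MYC. The two-sided exact permutation p was 0.1 for each of the 3 genes, the smallest that 3 arrays against 3 allow. CDK4 and MYC rest on 1 probe set each. Of 7 CDK6 probe sets, 6 fell past the threshold and a dim one at a mean level of 5.06 gave -0.14 (limma adjusted p = 0.333 over probe sets).

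**Figure D1:**
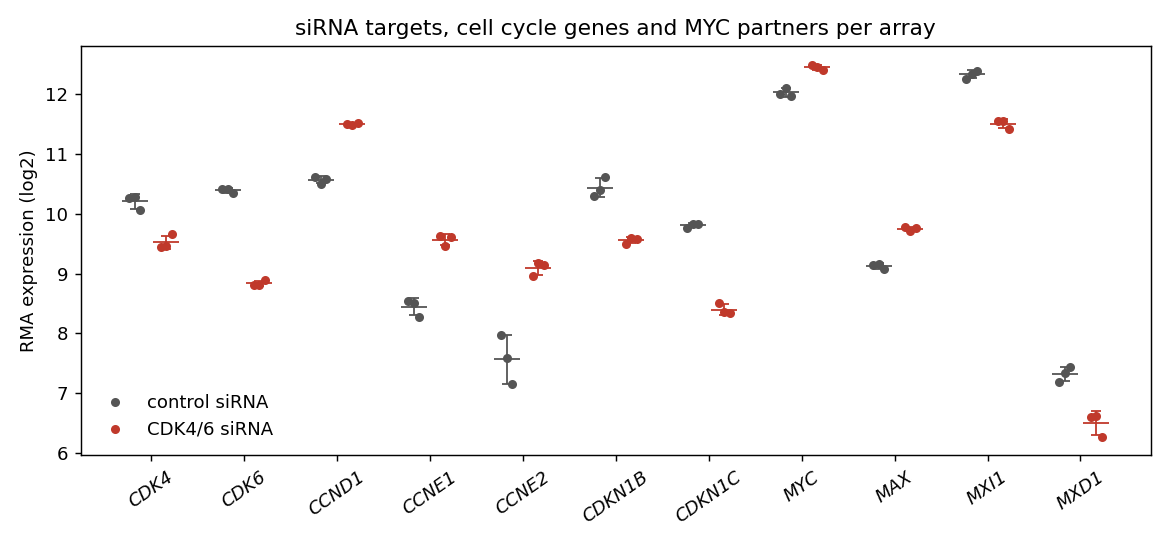
RMA expression on the log2 scale of the siRNA targets, cell cycle genes, MYC and MYC partner genes in each array (points: control siRNA in grey, CDK4/6 siRNA in red; horizontal marks: group means; bars: SD, n = 3). The 3 arrays of one group lie apart from the 3 of the other for each gene drawn, with CDK6 falling from 10.39 to 8.84 and CCND1 rising from 10.57 to 11.50.

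The largest rises included 4 kallikreins, a family of secreted serine proteases encoded side by side. KLK7 rose by 1.90 (3.74-fold, SE 0.070), KLK6 by 1.54, KLK10 by 1.44 and KLK5 by 1.35. A dim second probe set of KLK10, the one left when only probe sets with a plain name are used, gave -0.060 and did not pass. Cyclin E2 (CCNE2), which activates CDK2, rose by 1.53 (2.89-fold, SE 0.174). Also among the 12 were NRP1, a coreceptor for semaphorins and VEGF (2.83-fold), TIGAR, a fructose bisphosphatase that restrains glycolysis (1.45), CTPS1, which makes CTP (1.38), and WDR77, the partner of the arginine methyltransferase PRMT5 (1.38). GPATCH4 (1.42), ZBED2 (1.41) and LONRF2 (1.38) completed them. The probe sets of LONRF2, NRP1 and KLK5 were dim in control cells, at means of 4.89, 5.33 and 5.58. ANKRD37, a hypoxia-induced gene, fell furthest, by 1.92 (SE 0.073), to 26.4% of the control level. PDGFA, a growth factor, fell by 1.72, the chemokine receptor CXCR4 by 1.62, the arginase ARG2 by 1.57 and the fatty acid hydroxylase FA2H by 1.56. The other ARG2 probe set, with a plain name, gave -0.12 and did not pass, and the 2 other CXCR4 probe sets fell by 0.64 and 0.53. Dim probe sets, with mean levels under 6, did not pass for ANKRD37 (0.14), FA2H (-0.12), ZBTB18 (0.035), LONRF2 (0.16), CDKN1C (0.12), NRP1 (-0.086), PTCH1 (0.0022, -0.017 and -0.15), GPATCH4 (0.13, 0.080 and -0.073) and SSBP2 (-0.18, -0.12, -0.10 and 0.025). Others passed with smaller changes, for NRP1 (0.33 and 0.24), PTCH1 (-0.29) and SSBP2 (-0.47). CDK6 itself, SSBP2 (-1.52), the GTPase GEM (-1.48), the repressor ZBTB18 (-1.43), the interleukin-1 receptor subunit IL1RAP (-1.42), the CDK inhibitor CDKN1C (-1.41) and the Hedgehog receptor PTCH1 (-1.41) made up the rest. The limma adjusted p of these 24 genes ran from 7.19e-06 to 0.000351.

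**Figure D2:**
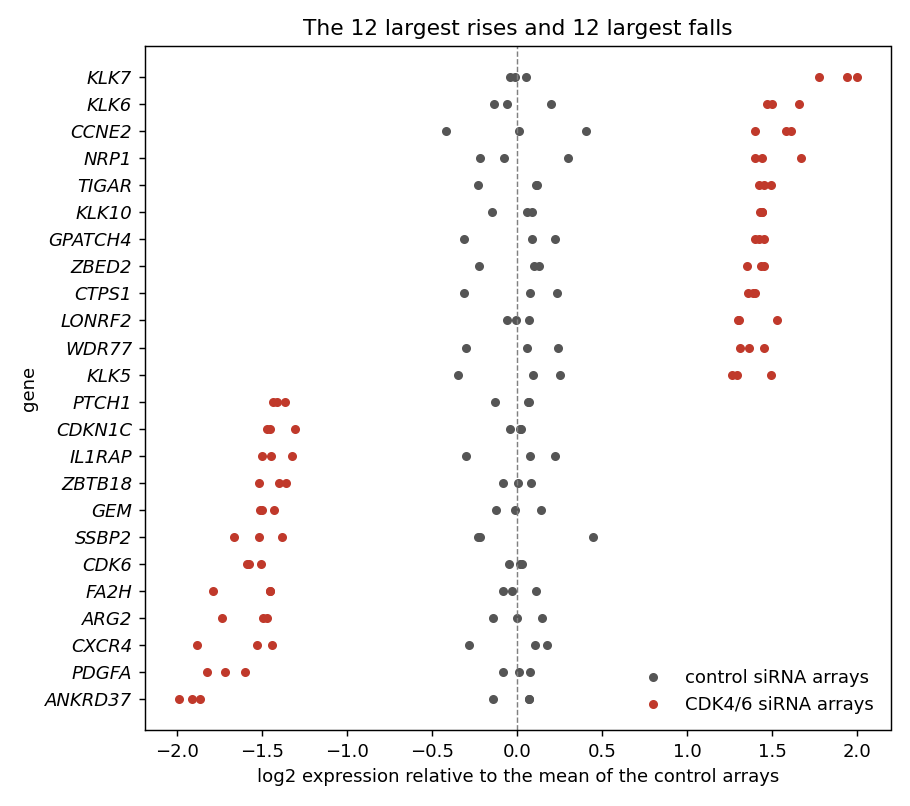
Log2 expression of the 12 largest rises and 12 largest falls in each array, relative to the mean of the 3 control arrays of the gene (grey points: control siRNA; red points: CDK4/6 siRNA). For each gene the 3 red points lie apart from the 3 grey points, from KLK7 (mean 1.90) at the top to ANKRD37 (mean -1.92) at the bottom.

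Across the transcriptome, limma called 5307 of 19775 genes changed, 2762 higher and 2545 lower (26.8% of genes). Most changes were small, with a median size of 0.35 on the log2 scale, and 108 genes changed at least 2-fold, 49 higher and 59 lower. With the mean of all probe sets of a gene in place of the brightest, 49 genes changed at least 2-fold. The groups did not overlap in 8085 genes (40.9%, against 10% by chance). The split between higher and lower depends on the scaling. The hybridisation spike-ins were lower by a log2 value of 0.11 in the CDK4/6 siRNA arrays (10.25 against 10.15), and with the arrays scaled to them the median of all genes moved to 0.11 and 4731 of 6051 called genes (78.2%) were higher, against 52.0% as deposited. Changes are given below relative to the bulk of the genes, as RMA leaves them.

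In the list of cyclin, CDK and CDK inhibitor genes, 9 of 27 measured genes were higher and 5 lower (9 and 5 adjusted over the list alone; 11 and 4 with the arrays scaled to the spike-ins). Cyclin E1 (CCNE1) rose by 1.12 and cyclin D1 (CCND1), the activator of CDK4 and CDK6, by 0.93, while the CDK inhibitors CDKN1C and CDKN1B fell by 1.41 and 0.88. Genes that go both ways left the list without a shift (limma's camera, adjusted p = 0.343).

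DNA replication genes were higher and mitosis genes lower in the CDK4/6 siRNA cells. Of 44 E2F-regulated DNA replication genes, 27 rose and 0 fell (28 and 0 adjusted over the list alone), with a list median of 0.39. Among them were MCM10 (1.11) and CDC6 (0.67), which act in loading and activating the replicative helicase, the GINS subunit GINS3 (0.66), and SLBP (0.45), which binds histone mRNA. Of 40 mitosis genes, 28 fell and 0 rose (30 and 0 adjusted over the list alone), with a list median of -0.31. With the arrays scaled to the spike-ins 19 mitosis genes fell and 0 rose, with a median of -0.20. They included the proliferation marker MKI67 (-0.72), the centrosomal kinase NEK2 (-0.71), the phosphatase CDC25C (-0.59), which activates CDK1, and the kinesin KIF20A (-0.56). On its probe set with a plain name CDC25C gave -0.058 and lost the call. Of 3 further MKI67 probe sets 1 fell by 0.50, and 2 at levels of 7.74 and 7.25 gave -0.0039 and 0.076 and did not pass. The limma camera adjusted p was 1.57e-08 for replication genes, with adjusted p = 0.65 with an estimated correlation, and 3.32e-12 for mitosis genes, with adjusted p = 0.34 with an estimated correlation. Per array, the mean of the replication genes minus the mean of the mitosis genes differed by 0.65 between the groups (exact permutation p = 0.1, n = 3 per group, the smallest possible). The controls were spread more widely on this value than the CDK4/6 siRNA arrays, which lay between -0.48 and -0.45. Control replicate 3 was the lowest at -1.27, and control replicate 2 gave -1.06. With 1 array left out the replication median ran from 0.31, without control replicate 3, to 0.42. The mitosis median then ran from -0.32 to -0.28. The size of the replication shift therefore depends in part on the control arrays used. Of 37 replication-dependent histone genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone), among them H2AC6 (0.87), H2BC12 (0.80), H2BC5 (0.50) and H2BC6 (0.44), without a list shift (camera adjusted p = 0.297). With the spike-in scaling 11 histone genes rose, and without variance moderation H2BC5 lost its call.

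Nucleolar and ribosome biogenesis genes listed beforehand as MYC-regulated gave the largest upward shift of the 27 lists. Of 34 measured, 30 rose and 0 fell (32 and 0 adjusted over the list alone), with a median of 0.57, or 1.49-fold. UTP20 (1.05), NOP16 (0.95), NIP7 (0.86) and RCL1 (0.71) all act in ribosomal RNA processing or ribosome assembly. On plain-name probe sets RCL1 (0.11) lost its call. Its limma camera adjusted p was 3.92e-18, and adjusted p = 0.34 with an estimated correlation. Genes of the MYC network itself went both ways, with 4 of 16 higher and 6 lower (4 and 6 adjusted over the list alone; 5 and 5 with the spike-in scaling; camera adjusted p = 0.497). MAX, the dimerisation partner of MYC, rose by 0.62, a call lost on plain-name probe sets (0.21), and MXI1 and MXD1, which compete with MYC for MAX, fell by 0.83 and 0.82, as did the kinase PIM1 by 0.81. Cytosolic ribosomal protein genes showed no list shift (camera adjusted p = 0.385). Of 67 genes written for the list 46 were measured, and of these 0 rose and 1 fell (0 and 0 adjusted over the list alone). The median was -0.012, or 0.096 with the arrays scaled to the spike-ins. RPS25, RPL18 and RPL36 had control means of 13.58, 13.57 and 12.91, with array maxima of 14.71 to 14.76. Whether changes are damped at such levels was not tested. RPLP2, dim at a control mean of 5.81, fell by 0.23 (limma adjusted p = 0.028) and lost its call with the spike-in scaling and without control replicate 1 (-0.20), control replicate 3 (-0.21), CDK4/6 replicate 2 (-0.22) or CDK4/6 replicate 3 (-0.23), while RPS25 (-0.19), RPL36 (-0.14) and RPL18 (-0.10) did not pass the threshold.

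Nucleotide synthesis genes were higher. Of 20 purine and pyrimidine synthesis genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.30, led by CTPS1 (1.38), UMPS (0.75), PPAT (0.52), which commits to purine synthesis, and DHODH (0.47). A dim probe set of PPAT, its only one with a plain name, gave -0.15 and did not pass, and on plain names UMPS (0.21) lost its call. For this list limma's camera gave an adjusted p of 3.38e-05, and adjusted p = 0.577 with an estimated correlation. In the glutamine and amino acid transporter list, which shares GMPS, CTPS1 and PPAT with it, 6 of 20 genes rose and 4 fell (8 and 4 adjusted over the list alone; 8 and 2 with the spike-in scaling; camera adjusted p = 0.456). SLC3A2, the shared chain of amino acid transporters, rose by 0.59 and GLUD1, glutamate dehydrogenase, fell by 0.38.

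Targets of hypoxia-inducible factors were the list with the largest downward shift. Of 28 measured HIF target genes, 23 fell and 2 rose (24 and 2 adjusted over the list alone), with a median of -0.71, a ratio of 0.611 to the control level. Besides ANKRD37, ANGPTL4, an inhibitor of lipoprotein lipase, fell by 1.13, the repressor BHLHE40 by 1.01 and PFKFB4, which sets the level of the glycolytic regulator fructose 2,6-bisphosphate, by 0.78. For HIF targets limma's camera gave an adjusted p of 4.38e-15, and adjusted p = 0.34 with an estimated correlation. Glycolysis genes were lower as well: 14 of 22 fell and 2 rose (15 and 3 adjusted over the list alone), with a median of -0.21, a camera adjusted p of 1.14e-05, and adjusted p = 0.34 with an estimated correlation. ENO2 fell by 1.28, the glucose transporter SLC2A3 by 1.22 and ALDOC by 1.13. Hexokinase HK2 fell by 0.67 on its bright probe set, at a mean level of 11.17, while its 2 dim probe sets rose by 0.72 and 0.62, and with the mean of its probe sets HK2 turned to 0.22 and lost the call. With the arrays scaled to the spike-ins, 9 glycolysis genes fell and 3 rose, with a median of -0.099.

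The remaining lists of carbon and lipid metabolism showed no list shift. In the pentose phosphate list 4 of 10 genes rose and 3 fell (4 and 3 adjusted over the list alone), including PRPS1 (0.49), PGD (0.41), RPIA (0.37) and H6PD (-0.40). Of 24 tricarboxylic acid cycle genes 4 rose and 3 fell (5 and 3 adjusted over the list alone), including IDH3A (0.36), DLAT (0.28), IDH2 (-0.64) and pyruvate carboxylase PC (-0.71). Of 48 oxidative phosphorylation genes 10 rose and 4 fell (12 and 4 adjusted over the list alone), including NDUFS6 (0.31), ATP5PB (0.29), NDUFS1 (0.27) and UQCRC1 (-0.29). Cholesterol and fatty acid synthesis genes were split, 6 of 22 higher and 4 lower (7 and 5 adjusted over the list alone), with the sterol sensor INSIG1 (-0.76), the carrier STARD4 (-0.65) and MSMO1 (-0.43) lower and LSS (0.35) higher. The limma camera adjusted p was 0.456, 0.497, 0.234 and 0.924 for these 4 lists. With the arrays scaled to the spike-ins the counts higher and lower were 6 and 1 for pentose phosphate, 9 and 2 for tricarboxylic acid cycle, 17 and 0 for oxidative phosphorylation and 7 and 4 for cholesterol genes. Calls were lost for PGD (0.11), H6PD (-0.17) and LSS (0.17) with the mean of their probe sets, for DLAT (0.30) and IDH2 (-0.20) on plain-name probe sets, for PRPS1 and RPIA without variance moderation, and for UQCRC1 (-0.18) with the spike-in scaling.

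Interferon-stimulated genes were higher. Of 39 measured, 19 rose and 2 fell (22 and 3 adjusted over the list alone), with a median of 0.25, or 0.48 with the dimmest genes left out, led by SAMD9 (1.35), IFI6 (1.02), the ubiquitin-like modifier ISG15 (0.77) and PARP9 (0.65), which lost its call on plain-name probe sets (0.20). The limma camera adjusted p was 1.90e-06, and adjusted p = 0.127 with an estimated correlation. Antigen presentation genes showed no list shift (camera adjusted p = 0.567). Of 19, 5 were higher and 3 lower (6 and 5 adjusted over the list alone, 7 and 2 with the spike-in scaling). HLA-DPA1 (1.26), PSMB10 (0.83) and the peptide transporter subunit TAP2 (0.50) were higher and PSMB9 (-0.48) lower. The HLA-DPA1 probe set was dim, at a control mean of 5.12.

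The counts of stress genes higher and lower depend on the scaling. Of 26 p53 target genes 7 rose and 6 fell (9 and 6 adjusted over the list alone; 11 and 2 with the arrays scaled to the spike-ins; camera adjusted p = 0.343), with TIGAR (1.45), TP53I3 (0.90) and TP53INP1 (0.64) higher and the DNA repair gene DDB2 (-0.81) lower. Of 26 ATF4 target and serine synthesis genes 3 rose and 6 fell (4 and 6 adjusted over the list alone; 6 and 4 with the spike-in scaling; camera adjusted p = 0.723), with the transcription factors DDIT3 (-0.98), ATF3 (-0.77) and CEBPB (-0.47) lower and the tryptophan tRNA synthetase WARS1 (0.75) higher. The only ATF3 probe set with a plain name gave 0.029 and did not pass. Endoplasmic reticulum chaperone genes were lower on balance, 9 of 19 falling and 3 rising (10 and 3 adjusted over the list alone), with a median of -0.17. EDEM1 (-0.89), which clears misfolded glycoproteins, the stress sensor ERN1 (-0.75), the cochaperone DNAJB9 (-0.59) and HERPUD1 (-0.37) fell. The limma camera adjusted p was 0.0115, with adjusted p = 0.354 with an estimated correlation. The call ended with the mean of all probe sets of a gene (adjusted p = 0.0782, within a range of 0.00456 to 0.0782 over the alternatives with a preset correlation), and with the arrays scaled to the spike-ins 4 genes fell and 4 rose, with a median of -0.058. A second ERN1 probe set gave -0.15 and did not pass. Lysosome and autophagy genes had 5 of 34 higher and 7 lower (6 and 7 adjusted over the list alone; 8 and 3 with the spike-in scaling; camera adjusted p = 0.567), with ATP6V0D1 (0.70), ASAH1 (0.50) and GLA (0.48) higher and the cholesterol exporter NPC1 (-0.49) lower.

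Markers of cell state changed gene by gene. In the list of epithelial and mesenchymal state genes 4 of 21 rose and 8 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.0568), with the mesenchymal genes TWIST1 (-0.87), FN1 (-0.77) and VIM (-0.63) lower and the epithelial keratin KRT8 (0.59) higher. FN1 lost its call on plain-name probe sets (-0.12). For genes named below, the next brightest probe sets of AXIN2 (0.0010) and COL1A1 (-0.075) did not pass. Senescence-associated secreted factor genes had 1 of 31 higher and 5 lower (1 and 5 adjusted over the list alone; camera adjusted p = 0.234), with the urokinase receptor PLAUR (-0.92), the chemokine CXCL8 (-0.79) and the cytokine LIF (-0.47) lower and IGFBP6 (0.67) higher. Among 32 intestinal differentiation genes 2 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.957), with KRT20 (0.75) higher and KLF4 (-0.97), DPP4 (-0.64) and CA2 (-0.31) lower. KRT20 was dim, at a control mean of 5.55. CA2 lost its call without control replicate 1 (-0.26) or control replicate 2 (-0.28) and with the arrays scaled to the spike-ins (-0.21). Of 19 Wnt target genes 5 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.726), with BMP4 (0.62), AXIN2 (0.54) and ZNRF3 (0.53) higher and the receptor FZD7 (-0.57) lower. Markers of other cell types showed no list shift: 0 of 14 fibroblast and endothelial markers rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.567), COL1A1 by 0.49, and 0 of 9 blood cell markers rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.456), HBB by 0.23. HBB lost its call without control replicate 2 (-0.21) or CDK4/6 replicate 3 (-0.20) and with the spike-in scaling (-0.12), and its probe set with a plain name gave 0.085. With the arrays scaled to the spike-ins the counts higher and lower were 4 and 3 for secreted factors, 4 and 2 for intestinal genes, 6 and 2 for Wnt targets, 2 and 1 for fibroblast and endothelial markers and 0 and 0 for blood cell markers. The other named markers gave FAP 0.15, LUM 0.11, TEK -0.14, MS4A1 -0.17, CD3D -0.08 and CD3E -0.07 as log2 fold changes, none past the threshold.

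**Figure D3:**
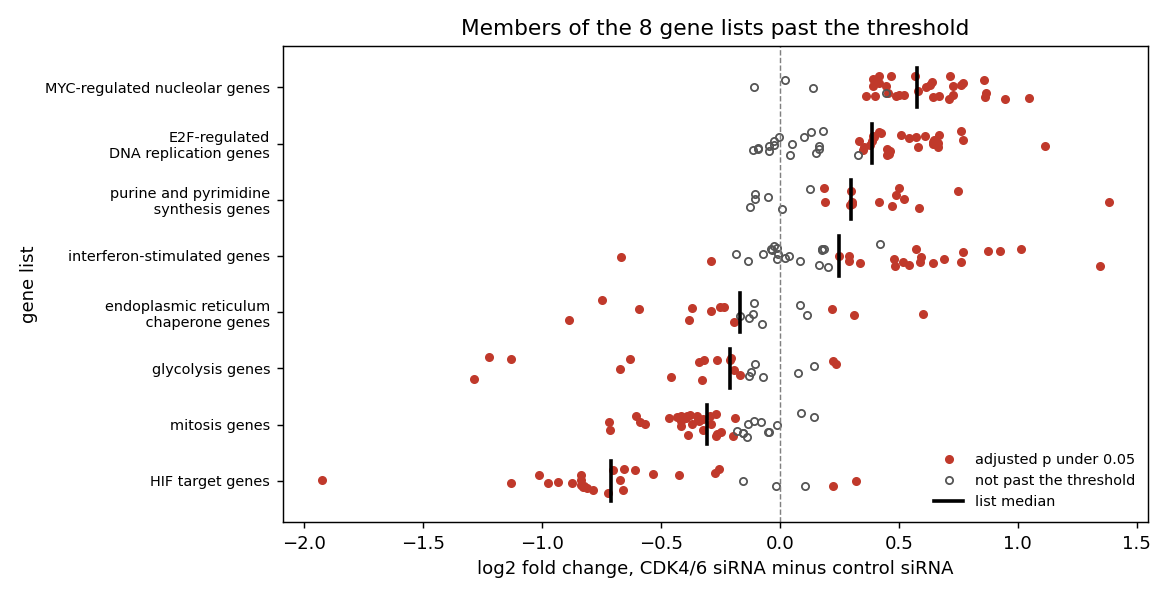
Log2 fold change (CDK4/6 siRNA minus control siRNA) of each measured member of the 8 gene lists that camera called with its preset correlation. Red points have a limma adjusted p under 0.05, open points do not pass it, and black bars are list medians. With an estimated correlation camera called 0 lists. MYC-regulated nucleolar genes have a median of 0.57 and HIF target genes a median of -0.71, and replication and mitosis genes lie on opposite sides of 0.

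Camera with its preset correlation called 8 of the 27 lists, 4 higher and 4 lower. Their estimated correlations were 0.73 for replication, 0.43 for nucleolar, 0.42 for nucleotide synthesis, 0.32 for HIF target and 0.24 for mitosis genes. They were 0.15 for glycolysis, 0.047 for endoplasmic reticulum and 0.0027 for interferon genes, against the preset 0.01. With an estimated correlation camera called 0 lists, with 2 at an unadjusted p under 0.05, and camera on ranks called 8. The test fry called 16, and it asks only whether a list's genes move one way and not whether they differ from other genes. Of lists that camera did not call, fry called antigen presentation, histone, p53 target and pentose phosphate genes higher. It called secreted factor, cytosolic ribosomal protein, ATF4 target, and epithelial and mesenchymal genes lower. Median, mean and test differed in sign for 4 lists without a shift, ATF4 targets (0.017, -0.031, lower), cholesterol genes (0.049, -0.015, higher), intestinal genes (0.026, -0.016, lower) and Wnt targets (-0.012, 0.035, higher). Of 7318 other probe sets of called genes, 75.6% had the sign of the probe set that stood for the gene, and of the 2509 past the threshold 167 had the opposite sign.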

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

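The test of flanking genes against the 5 kallikreins that rose, and the comparison of gene counts between splits, were chosen after their results were seen; the other tests here were chosen after the pattern but before their own result was seen.

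Probe sets outside the gene comparison also changed. Of 13522 probe sets that name no single gene, 1274 passed the limma threshold, 594 higher and 680 lower, or 9.42% against 19.5% of the probe sets that name a gene. The furthest of them in each direction fell by 2.13, from 8.05 to 5.92, and rose by 1.83, from 4.11 to 5.94. The 18 hybridisation spike-in probe sets differed by -0.11 between CDK4/6 siRNA and control arrays (10.15 ± 0.05 against 10.25 ± 0.02, SD, n = 3, exact permutation p = 0.1, the smallest possible). The 27 poly-A control probe sets differed by 0.022 (exact permutation p = 0.6) at a median level of 3.63, near the floor.

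Replication genes were higher and mitosis genes lower in the same cells. With an estimated correlation neither list was called (limma's camera, adjusted p = 0.65 and 0.34). A bias that depends on signal level is argued against, since the list medians lay beyond the central 95% of level-matched random lists by at least 0.24. Probe sequence shared between genes is argued against, since the distance between the list medians was 0.68 on probe sets with a plain name and 0.70 on all. RNA degradation is argued against, since the 3'-to-5' signal difference changed by -0.014 for ACTB and 0.011 for GAPDH, less than the spread between replicates. A hypothesis left open is that the CDK4/6 siRNA cells spent more of their cycle in S phase and less in mitosis, which these arrays cannot test.

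HIF target genes fell as a group, and glycolysis genes, which share HK2 and SLC2A1 with that list, were lower as well. Neither list was called with an estimated correlation (limma's camera, adjusted p = 0.34 for each). A bias that depends on signal level is argued against, with the list median 0.64 below the range of level-matched lists, and so is RNA degradation (-0.014, as above). A lower HIF1A transcript is argued against, since HIF1A rose by 0.26 (95% interval 0.14 to 0.38, limma adjusted p = 0.0067). The partner ARNT fell by 0.62 and EPAS1 by 0.50, read after the result was seen. It stays open whether less HIF protein, another oxygen supply in culture or the siRNAs acting on unintended transcripts lies behind the fall. The lower ARNT and EPAS1 transcripts stay open as a cause too. With 1 siRNA mix set against 1 control mix, these cannot be told apart.

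The kallikreins KLK5, KLK6, KLK7, KLK8 and KLK10 rose, with a median of 1.44, and the same number of kallikreins rose with the arrays scaled to the spike-ins, while the median of all 14 measured was -0.002. A change of the whole chromosome region was first tested against that median of all 14, a poor bound because only 11 of 33 kallikrein probe sets had a mean level over 6; the 20 flanking genes had a median of -0.0094, with 0 past the limma threshold and 0 at an unadjusted p under 0.05. Against the 5 that rose, the 4 flanking genes with a mean level over 6 had a median of 0.011 (bootstrap interval -0.10 to 0.067). With 4 genes and no detection calls, this cannot decide whether the region changed. Probe sequence shared by all kallikreins is argued against, since 6 of 11 kallikrein probe sets with a level over 6 had intervals that lay under 50% of the largest rise. Of the genes that rose, only KLK8 is among these. Sequence shared among KLK5, KLK6, KLK7 and KLK10 is therefore not addressed. A shared regulation of these 5 genes in the CDK4/6 siRNA cells remains a hypothesis.

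The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 of the 10 splits, the real one, gave 5307 calls, and the highest of the others gave 0, with 299 to 530 genes at an unadjusted p under 0.05. For lists, 2 of the 10 splits called 8 lists, the real one and the split that puts control replicates 1 and 3 with CDK4/6 replicate 2, and the remaining splits called from 2 to 7. Each split other than the real one keeps part of the difference between the groups, so these counts do not show what would be called without one.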

How the results depend on the processing

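Scaling to the spike-ins and the use of probe sets with a plain name only were chosen after seeing the data. CDK4, CDK6 and MYC kept their direction and stayed past the threshold in all of their 17, 18 and 17 alternatives, at -0.75 to -0.58, -1.58 to -1.24 and 0.39 to 0.53. The replicate numbers do not pair the arrays, since deviations from the group means correlated at -0.010, -0.12 and -0.0066 for arrays of the same number; with a replicate block 4738 genes were called, 4601 of them shared with the 5307. Leaving out 1 array at a time gave 4225 to 4726 genes and 82 to 138 genes at 2-fold, 0 of 119 named called genes reversed, and 3 lost the call (CA2, HBB and RPLP2, with values in the report). A threshold of 0.01 left 3326 genes, and the test without variance moderation 4036. The mean of all probe sets of a gene left 49 genes at 2-fold, turned HK2 to 0.22 and MS4A1 to 0.0015, took the endoplasmic reticulum list to -0.14 (adjusted p = 0.0782, past the threshold under 15 of 16 alternatives with a preset correlation, 0.00456 to 0.0782), and changed the sign of the median or of the test for lists without a shift, ATF4 targets (median 0.028), cholesterol (-0.0025), antigen presentation (-0.017), intestinal (0.020) and Wnt (-0.026) genes. Probe sets with a plain name turned KLK10 (-0.060), PPAT (-0.15), ATF3 (0.029) and HBB (0.085), for each of which that leaves a dimmer probe set, and ended the calls of ARG2, CDC25C, DLAT, FN1, IDH2, MAX, PARP9, RCL1, RPLP2 and UMPS without turning them. The mean of probe sets ended those of H6PD, LSS, PGD and RPLP2, the test without moderation those of CA2, H2BC5, PRPS1, RPIA and RPLP2, and spike-in scaling those of CA2, HBB, RPLP2 and UQCRC1. Scaling to the spike-ins, which adds one shift to all genes, turned RPL18 (0.0054), CD3D (0.031) and CD3E (0.034) and the medians of the ribosomal protein (0.096), epithelial and mesenchymal (0.017), MYC partner (0.077), lysosome (0.072), secreted factor (0.062), Wnt (0.096), fibroblast and endothelial (0.082) and blood cell (0.047) lists, all without a call. The cholesterol list changed the direction of its test or of its median, at 0.053 with quantile normalisation, 0.041 with cyclic loess, 0.043 with array weights, 0.031 with plain probe sets, 0.16 with spike-in scaling, 0.049 with fry, 0.028 without control replicate 3 and 0.020 without CDK4/6 replicate 1; its range with 1 array left out was 0.020 to 0.067. The intestinal list did so at 0.026 with the replicate block, 0.032 with quantile normalisation, 0.030 with cyclic loess, 0.025 with array weights, 0.030 with plain probe sets, 0.13 with spike-in scaling, 0.026 with camera on ranks, 0.014 without control replicate 3 and 0.019 without CDK4/6 replicate 1, within a range of -0.0054 to 0.020 with 1 array left out, and ATF4 targets at 0.017 on ranks. The cause was not tested for these lists. Camera with an estimated correlation called 0 lists and fry 16. The medians stay as they were under that camera setting (replication 0.39, mitosis -0.31, nucleolar 0.57, glycolysis -0.21, HIF -0.71, endoplasmic reticulum -0.17, nucleotide synthesis 0.30, interferon 0.25). Its adjusted p for these lists, in that order, was 0.65, 0.34, 0.34, 0.34, 0.34, 0.354, 0.577 and 0.127. For the interferon list the estimated correlation was 0.0027, below the preset 0.01, while the unadjusted camera p went from 3.52e-07 to 0.0047. A higher correlation therefore does not account for the lost interferon call. Apart from the endoplasmic reticulum list, the other 7 called lists were past the threshold in all 16 alternatives with a preset correlation. Signal near the floor limits dim genes, whose changes RMA compresses.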

Other observations

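The gene families in this part were chosen after the results above were seen, and the neighbour and FOXO tests were chosen before their own results were seen.

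Families of ribosome assembly, RNA synthesis and RNA processing had more genes higher than lower. The cytosolic ribosomal protein list had 0 of 46 measured genes higher, out of 67 written, many of them bright. The families were gathered by symbol stem, and antisense transcripts, pseudogenes and genes that only share the stem were left out after the first counts were seen. Of 75 mitochondrial ribosomal protein genes 50 rose and 0 fell (median 0.27), led by MRPS23 (0.84) and MRPS12 (0.69). All 10 measured UTP genes of the small subunit processome, which include UTP20, rose, with UTP15 at 0.99. RNA polymerase I, which transcribes ribosomal RNA, had 6 of 8 subunit genes higher and 1 lower, with POLR1A at 0.97, and RNA polymerase III 7 of 9 higher and 1 lower, with POLR3B at 1.06. The exosome, which trims RNA, had 6 of 10 genes higher and 0 lower, with EXOSC4 at 0.89. Translation initiation factor genes had 16 of 41 higher and 4 lower, with a median of 0.17, or 0.27 with the arrays scaled to the spike-ins. Outside these functions, the proteasome had 18 of 31 subunit genes higher and 1 lower, with PSMA5 at 0.51 (median 0.21, or 0.31 with the spike-in scaling), the CCT chaperonin 5 of 8 higher and 0 lower, with CCT2 at 0.36, and V-type ATPase genes, for proton pumps of acidic compartments, 8 of 20 higher and 0 lower (13 and 0 with the spike-in scaling). Kinesin genes had 2 of 38 higher and 11 lower (median -0.14; 6 and 8 with a median of -0.035 with the spike-in scaling), and histone demethylase KDM genes 1 of 18 higher and 8 lower, with KDM3A at -0.72 and KDM7A at -0.56 (1 and 5 with the spike-in scaling, where the median moved from -0.21 to -0.10). Some members also sit in lists reported above. KDM3A and KDM4B are in the HIF target list, and KIF11, KIF14, KIF20A, KIF23, KIF2C and KIF4A are in the mitosis list. POLR1B is in the nucleolar list, PSMB8, PSMB9 and PSMB10 in the antigen presentation list and ATP6V0D1, ATP6V1A and ATP6V1H in the lysosome list. These families are therefore not independent of those lists. Of the 18 families, limma's camera called 14 with its preset correlation, 11 higher and 3 lower. With an estimated correlation it called 0, where 5 had an unadjusted p under 0.05 and the lowest adjusted p was 0.159.

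PDK4 (-1.41), TSC22D3 (-1.34), DEPP1 (-1.22) and ARRDC3 (-1.22) fell, named after their values were seen, and all 4 are known FOXO targets. The hypothesis of FOXO target genes lower as a group was tested on 20 other FOXO targets, of which 10 fell and 3 rose. Those that fell included CCNG2 (-0.75), KLHL24 (-0.83), BCL6 (-0.67) and IRS2 (-0.66), and those that rose were ARRDC4, BCL2L11 and TRIB1. The median of -0.25 lay at percentile 0 of 10000 level-matched random lists. Such lists draw genes without regard to their correlation, so the percentile does not allow for targets that vary together. With the arrays scaled to the spike-ins 8 fell and 3 rose, with a median of -0.15. The limma camera adjusted p was 0.00333 over the families, and adjusted p = 0.308 with an estimated correlation. Lower FOXO activity is a candidate explanation, and FOXO protein was not measured.

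Genes that neighbour each other on a chromosome may change together. The hypothesis that genome neighbours move together beyond chance was tested on windows of 7 measured neighbours among 19734 placed genes. The variance of the window means was 1.09 times the highest of 1000 shuffles of gene order, and 1.06 times with 1 gene kept per name stem and chromosome. The stems do not join a gene with its antisense transcript, so such pairs still count in the second value. Windows beyond the highest shuffled mean of 0.64 were the kallikreins from KLK2 to KLK10 (mean 0.96, 5 of 7 past the limma threshold) and the window around ANKRD37 (mean -0.85, 7 of 7 lower, 6 with the arrays scaled to the spike-ins). Kallikreins and ANKRD37 were already known to be among the largest changes, so these windows are not independent of that result. In chromosome order SNX25 fell by 0.40, LRP2BP by 0.85, ANKRD37 by 1.92, UFSP2 by 0.31, CFAP96 by 0.98, CCDC110 by 0.74 and PDLIM3 by 0.75. Genes on both sides of ANKRD37 fell, so transcription running on from ANKRD37 in one direction would not account for the whole window, and the cause was not tested.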
